A study of Mus musculus with 8 samples.

How the data were processed

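Polyadenylated RNA of RAW264.7 cells, a mouse macrophage-like line, was sequenced in 8 libraries. The labels place them in 4 groups of 2: solvent alone (mock), Tubuloside B alone (TubB), lipopolysaccharide at 10 ng/ml with interferon-gamma at 20 ng/ml for 24 h (LPS_IFNg), and that stimulus with Tubuloside B (LPS_IFNg_TubB). Per the labels' protocols, the library kit did not keep the strand of the RNA. The dose of Tubuloside B was not given in the sources used here. The labels gave a time only for the groups with the stimulus, and none for mock or TubB.

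The authors deposited a table of raw read counts per gene for all 8 libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7.0 and counted with featureCounts. Per the file headers, featureCounts was version 2.0.1, counted paired reads over exons by gene, used an NCBI RefSeq annotation of the mouse assembly GRCm38.p6, and was given no option for strand or for reads that map to several places. Under the program's defaults such a call counts both strands together and leaves multi-mapped reads out, so antisense genes cannot be told from the genes they overlap. The deposited table also gives a gene length in bases per the file headers, the summed exon length, which was used only to choose genes by length in the closing section. The table had 42454 rows, of which 18955 held at least 1 count. Of the gene symbols, 1740 also occurred with a numbered copy elsewhere in the assembly, and 1239 of these held 0 counts over all 8 libraries, including Tnf and most major histocompatibility genes. The authors also deposited a table of regularised log2 values (rlog) for the same 18955 genes. It was used as an alternative and to check the numbering of the columns. Columns were assigned through the library number that opens each label.

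Counts summed to between 4767894 and 8413834 per library. Counting error is therefore small for genes above about 3 log2 CPM and large for genes with single counts. Intervals and floors at low counts cover counting error only, because reads without molecular identifiers are not independent molecules. A gene without counts in a group was given a floor of 3 counts over the 2 libraries of that group, and a ratio to 1 to 3 counts was given with its exact 95% interval.

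The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM normalisation, the filterByExpr filter by group (minimum count 10, minimum total 15), robust estimation, all 8 libraries and the group as the only term, which left 4 residual degrees of freedom before the spread was shared across genes. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The filter kept 11081 genes. Levels are CPM, the counts scaled by edgeR to a common library size with TMM factors, and errors of log2 fold changes are standard errors (SE) obtained from the fold change and its F statistic. The 5 planned contrasts follow. LPS_IFNg minus mock and LPS_IFNg_TubB minus TubB give the stimulus without and with the compound. TubB minus mock and LPS_IFNg_TubB minus LPS_IFNg give the compound without and with the stimulus. The interaction is the difference of the compound's 2 effects. LPS_IFNg_TubB minus mock was added after the data were seen.

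Gene lists, 49 in all, the named-gene rule, the tests and most alternatives were fixed before the data were examined. Lists with at least 3 measured members, 39 of the 49, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera has only the 4 residual degrees of freedom of the design. A missing call there cannot tell an unchanged list from low power. The 10 other lists, among them all markers of other cell types, had too few measured members. Named genes were, per contrast, the 5 largest rises and 5 largest falls among called genes with a mean of at least 3 log2 CPM and no overlap between the libraries of the groups, leaving out unnamed models and pseudogenes. For each list described, up to 4 called members with the largest fold change were named, or 2 with the smallest p where none was called. The 10 markers Tnf, Il6, Il1b, Nos2, Ptgs2, Ccl2, Cxcl10, Il10, Arg1 and Hmox1 were named whatever their values.

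Alternatives were RLE in place of TMM factors, no count filter, a filter of 1 CPM in 2 libraries, the compared groups alone, the replicate number as a block, DESeq2 1.42.0, limma-voom, limma on the rlog values, a 2-fold minimum and leaving out each library. The block within only the compared groups was added after the data were seen. The fits were tested on counts simulated from real means and spread, with compared groups set equal except for 200 changed genes per contrast. For the interaction, TubB was given the means of mock and LPS_IFNg_TubB those of LPS_IFNg, unlike the data. In these simulations, edgeR recovered 77.6% of 67 genes changed 2-fold and 97.0% of 66 changed 4-fold for LPS_IFNg minus mock (10959 genes), 88.1% and 90.9% for LPS_IFNg_TubB minus TubB (10943 genes), and 64.2% and 89.4% for the interaction (10676 genes). Of 67 genes changed 1.5-fold, it recovered 50.75%, 49.25% and 38.81% in the same order. Unchanged genes made up 8 of 158 calls, 22 of 174 and 7 of 135 in these 3 contrasts, so the share of false calls was above the threshold of 0.05 in each. They made up 8 of 161 calls for LPS_IFNg_TubB minus LPS_IFNg, 10 of 155 for TubB minus mock and 6 of 157 for LPS_IFNg_TubB minus mock. Each contrast was simulated 1 time, so shares near 0.05 cannot be told from it.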

Results

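RNA of RAW264.7 cells, a mouse macrophage-like line derived from a virus-induced tumour, was sequenced in 8 libraries, 2 in each of 4 labelled groups. The groups cross a stimulus with a compound. The stimulus was lipopolysaccharide (LPS, a bacterial cell wall component sensed by Toll-like receptor signalling) with interferon-gamma (IFN-γ), a pairing that drives macrophages towards inflammatory activation. The compound was Tubuloside B, a phenylethanoid glycoside. Library totals ranged from 4767894 counts (LPS_IFNg_TubB replicate 1) to 8413834 (TubB replicate 2). Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples only.

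The stimulus markers did not follow the labels. Nos2 (inducible nitric oxide synthase; chromosome 11, 78920787 to 78960226, GRCm38.p6) had 165 ± 14.6 CPM (SD, n = 2) in the libraries labelled mock, 182 ± 23.2 in those labelled LPS_IFNg, 6352 ± 849 in those labelled TubB and 6781 ± 899 in those labelled LPS_IFNg_TubB. Ptgs2 (cyclooxygenase 2; chromosome 1, 150100031 to 150108234) had 43.6 ± 0.382, 43.9 ± 1.22, 1778 ± 599 and 1753 ± 412 CPM in the same order. Il6 (chromosome 5, 30013114 to 30019975) had 1 count over both libraries labelled mock and 0 over both labelled LPS_IFNg, against 613 over those labelled TubB and 568 over those labelled LPS_IFNg_TubB. Of 70 measured members of the type I interferon, IFN-γ and classical activation lists, 0 were called between the libraries labelled LPS_IFNg and mock, and 69 were higher in those labelled TubB than in mock. Samples keep their deposited labels throughout. Every direction given here for TubB or LPS_IFNg is a difference between libraries so labelled, and stands under this conflict between label and marker genes.

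**Figure D1:**
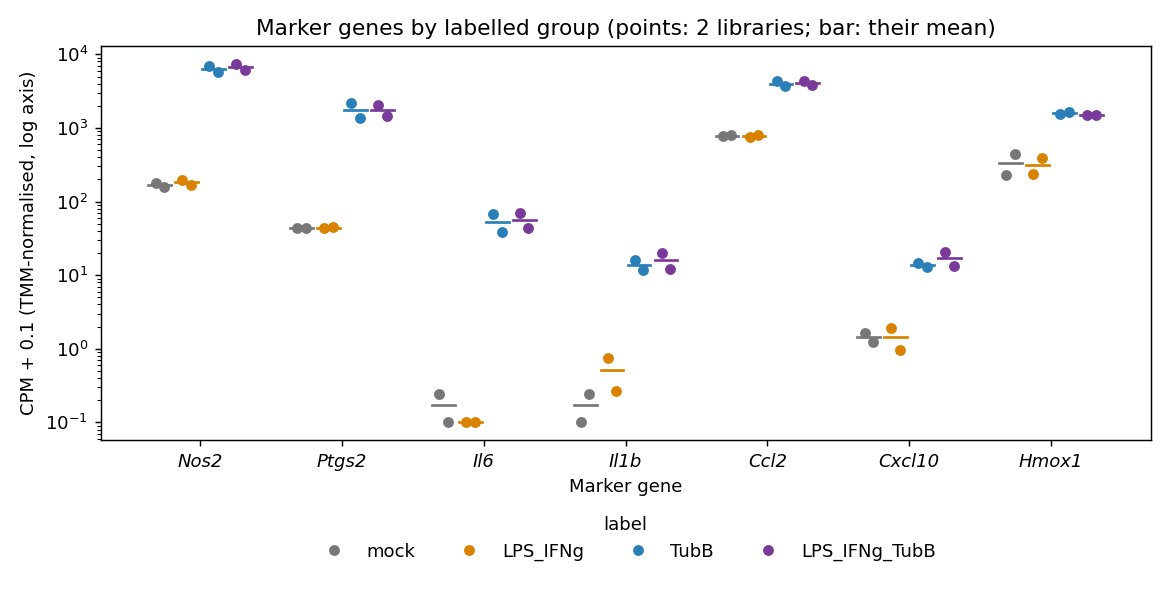
Levels of the 7 measured marker genes in TMM-normalised CPM plus 0.1 on a log axis, with 1 point per library and a bar at the mean of the 2 libraries of each labelled group. The libraries labelled LPS_IFNg sit beside those labelled mock (Nos2 182 against 165 CPM), and those labelled TubB beside those labelled LPS_IFNg_TubB (6352 against 6781 CPM).

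The first principal component of log2 CPM held 83.6% of the variance and placed the libraries labelled mock and LPS_IFNg at one end and those labelled TubB and LPS_IFNg_TubB at the other. Counts of no pair of libraries agreed within sampling noise, for which the mean chi-square per gene is 1. The closest pairs joined libraries of different labels with the same replicate number. This value was 2.03 and 1.96 for mock with LPS_IFNg (replicates 1 and 2) and 1.99 and 2.47 for TubB with LPS_IFNg_TubB. It was 3.15, 2.73, 5.67 and 3.69 between the replicates of mock, LPS_IFNg, TubB and LPS_IFNg_TubB.

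The contrast of TubB with mock asks what Tubuloside B does without the stimulus, as labelled. Interferon-inducible genes were higher by the largest margins in the libraries labelled TubB. Serpina3g, a serine protease inhibitor (chromosome 12, 104236147 to 104241939), had 0 counts in mock and 422 ± 47.6 CPM in TubB, at least 1941-fold higher against a floor of 3 counts over the group. Iigp1 and Gbp5, GTPases that act against intracellular pathogens, had 1 count each in mock, and were 9551-fold (95% interval 1714 to 377300) and 8173-fold (1466 to 322900) higher. Gbp2b was higher by 12.45 ± 0.38 and Serpina3f by 11.53 ± 0.18 on the log2 scale. These SEs understate the error, because leaving out 1 mock library moved each fold by more than its SE, as given below. The largest falls were in Igfbp4, an insulin-like growth factor binding protein (-3.47 ± 0.15), Cx3cr1, the fractalkine receptor (-3.16 ± 0.21), Ptgs1, cyclooxygenase 1 (-2.86 ± 0.17), Sapcd2 (-2.67 ± 0.25) and Tfap4 (-2.60 ± 0.24). Of 11081 genes, edgeR called 2916 higher and 2755 lower. With a 2-fold minimum these were 1103 and 626. The Gbp, Iigp and Serpina3 families hold close paralogs, so levels of single members are uncertain where reads were shared. Without mock replicate 1, Gbp2b had 0 counts left in mock and was at least 4671-fold higher, Iigp1 and Gbp5 also had 0 and were at least 1565-fold and 1340-fold higher, Serpina3g was at least 955-fold higher, and Serpina3f was 5164-fold higher (95% interval 1429 to 42640). Without mock replicate 2, Gbp2b stood at 11.51, Iigp1 was 4854-fold (871 to 191800) and Gbp5 4154-fold (745 to 164100) higher, and Serpina3g was at least 987-fold higher. Without TubB replicate 2, Cx3cr1 stood at -3.83 and Tfap4 at -3.32. A bound against a group at 0 is lower by its construction when 1 library of that group is left out, because the floor of 3 counts then rests on 1 library.

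All 37 measured members of the type I interferon list of 39 were higher in the libraries labelled TubB, with a median of 3.76 on the log2 scale (camera adjusted p = 1.22e-16). With an estimated correlation the adjusted p = 0.308. Zbp1, a sensor of Z-form nucleic acids, was higher by 7.70 ± 0.22, Oasl2 by 8.02 ± 1.03 and the antiviral Rsad2 by 7.35 ± 0.89. Ifi44l had 0 counts in mock and was at least 36.1-fold higher, or at least 20.1-fold without TubB replicate 1 and 64.0-fold without TubB replicate 2, and at least 17.7-fold or 18.3-fold without mock replicate 1 or 2. All 18 measured members of the 24 IFN-γ-inducible GTPases and regulators were higher (adjusted p = 2.26e-16, and adjusted p = 0.186 with an estimated correlation), with a median of 8.52, or 8.01 with the 8 members of few counts at their bound or count ratio. Gbp6 and Tgtp1 were at least 490-fold and 320-fold higher, or 241-fold and 157-fold without mock replicate 1 and 249-fold and 163-fold without mock replicate 2. All 9 measured class I antigen presentation genes were higher (adjusted p = 2.78e-08, and adjusted p = 0.186 with an estimated correlation), led by H2-T23 (3.93 ± 0.18), Tapbpl (3.84 ± 0.17), the transactivator Nlrc5 (3.73 ± 0.10) and the immunoproteasome subunit Psmb10 (3.48 ± 0.12). The other 11 of that list, and 9 of 12 class II genes, were too low to test, and 13 and 9 members of these lists have a numbered copy in the assembly. Of the 3 measured class II genes, Ctss rose by 1.98 ± 0.07 and Cd74 by 0.81 ± 0.11, and the list was called by fry (adjusted p = 0.000260) but not by camera (adjusted p = 0.103), except without mock replicate 2 (adjusted p = 0.0357), TubB replicate 1 (0.0428) or LPS_IFNg replicate 2 (0.0497). Without mock replicate 1, Zbp1 was 345-fold higher (95% interval 118 to 1676) and Oasl2 169-fold (57.6 to 820). Without mock replicate 2, Oasl2 was 524-fold higher (93.7 to 20700), and without TubB replicate 1, Rsad2 stood at 6.64.

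Of 11 measured cytokines, 10 were higher and 0 lower in the libraries labelled TubB (adjusted p = 4.60e-06, and adjusted p = 0.272 with an estimated correlation). Il6 and Il1b had 1 count each in mock and were 691-fold (95% interval 124 to 27330) and 187-fold (33.1 to 7432) higher. Il27 was higher by 6.13 ± 0.48 and the granulocyte growth factor Csf3 by 5.84 ± 0.16. Of 11 measured chemokines, 9 were higher (adjusted p = 8.30e-07, and adjusted p = 0.272 with an estimated correlation). Ccl12 and Cxcl9 had 0 counts in mock and were at least 134-fold and 36.1-fold higher, Ccl5 was higher by 4.72 ± 0.37 and Ccl7 by 3.39 ± 0.08. Ccl2 rose from 789 ± 31.9 to 4010 ± 488 CPM and Cxcl10 from 1.34 ± 0.269 to 13.7 ± 1.10 CPM (log2 2.35 ± 0.08 and 3.32 ± 0.36). Il10 and Tnf had 0 counts in each of the 8 libraries, and Arg1 had at most 5 counts in any group, so none of these could be compared. Tnf lies at chromosome 17, 35199367 to 35202007, and has a numbered copy in the assembly, so its 0 is not evidence that the gene was silent. Without mock replicate 1, Il6 was at least 113-fold and Il1b 92.0-fold (95% interval 16.3 to 3655) higher, and Ccl12 and Cxcl9 at least 66.1-fold and 17.7-fold. Without mock replicate 2, Il6 was 351-fold (62.8 to 13890) and Il1b at least 31.7-fold higher, and Ccl12 and Cxcl9 at least 68.3-fold and 18.3-fold.

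All 22 measured NF-κB targets and feedback genes were higher (adjusted p = 3.70e-12, and adjusted p = 0.186 with an estimated correlation), among them Traf1 (6.66 ± 0.45), Cd40 (6.22 ± 0.34), the adhesion molecule Icam1 (3.17 ± 0.11) and the feedback enzyme Tnfaip3 (2.97 ± 0.13). Of 15 measured classical activation genes, 14 were higher (adjusted p = 1.16e-08, and adjusted p = 0.186 with an estimated correlation). Nos2 rose by 5.26 ± 0.16 and Ptgs2 by 5.35 ± 0.37, Gpr18 by 4.88 ± 0.38, and the formyl peptide receptor Fpr2, with 0 counts in mock, was at least 225-fold higher. Negative regulators of inflammation were higher too, 17 of 18, with 1 lower (adjusted p = 1.68e-09, and adjusted p = 0.186 with an estimated correlation). These included the cytokine signalling inhibitors Socs1 (6.80 ± 0.35) and Socs3 (4.35 ± 0.09), the checkpoint ligand Cd274 (5.50 ± 0.21) and the phosphatase Dusp1 (4.03 ± 0.27). Inflammasome and cell death genes were higher in 13 of 14, with Casp4 at 3.30 ± 0.15 and Casp1 at 2.57 ± 0.11 (adjusted p = 8.01e-08, and adjusted p = 0.186 with an estimated correlation). In the list named alternative activation all 5 measured genes were higher (adjusted p = 0.000318, and adjusted p = 0.272 with an estimated correlation). Clec7a (2.32 ± 0.35), Myc (2.30 ± 0.16), Il4ra (2.27 ± 0.26) and Tgm2 (2.16 ± 0.11) were among them. The other 17 members of the list, Arg1 among them, were too low to test, and Myc and Il4ra also respond to other signals. Without mock replicate 1, Socs1 had 0 counts left in mock and was at least 112-fold higher, and Fpr2 was at least 111-fold higher. Without mock replicate 2, Socs1 stood at 5.85 and Fpr2 was at least 114-fold higher.

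Metabolic genes moved both ways in the libraries labelled TubB. Of 23 measured glycolysis genes, 19 were higher and 3 lower (adjusted p = 1.46e-05, and adjusted p = 0.317 with an estimated correlation), with the hexokinase Hk3 at 2.15 ± 0.07, the glucose transporter Slc2a1 at 2.14 ± 0.16, Pfkfb3 at 1.59 ± 0.13 and the lactate transporter Slc16a3 at 1.52 ± 0.09. Hypoxia-inducible factor targets were higher in 16 of 20 and lower in 1 (adjusted p = 3.52e-06, and adjusted p = 0.320 with an estimated correlation), led by P4ha2 (4.56 ± 0.66), Ankrd37 (4.11 ± 0.55), Ndrg1 (3.52 ± 0.44) and Bnip3 (3.43 ± 0.40). Of 21 tricarboxylic acid cycle genes, 12 were lower and 0 higher (adjusted p = 0.000318, and adjusted p = 0.308 with an estimated correlation), with Idh2 at -1.35 ± 0.10, Suclg2 at -1.01 ± 0.10, Fh1 at -1.01 ± 0.10 and Idh3a at -0.85 ± 0.08. Nuclear genes of oxidative phosphorylation were lower in 12 and higher in 3 of 39 (adjusted p = 0.0350, and adjusted p = 0.552 with an estimated correlation), and this call was lost without mock replicate 2 (adjusted p = 0.0881) or TubB replicate 2 (0.184). Of 24 cholesterol synthesis genes, 12 were lower and 1 higher (adjusted p = 0.00207, and adjusted p = 0.373 with an estimated correlation). The liver X receptor targets were called lower as a list by fry (adjusted p = 0.0152) but not by camera (adjusted p = 0.0528), with 8 of 12 lower and 1 higher, with the desaturases Scd1 at -2.19 ± 0.26 and Scd2 at -1.36 ± 0.20. Camera called the list without mock replicate 2 (adjusted p = 0.0344), TubB replicate 2 (0.0429), LPS_IFNg replicate 1 (0.0484) or LPS_IFNg replicate 2 (0.0485). P4ha2 stood at 3.57 without mock replicate 1 and 3.89 without TubB replicate 1, and without mock replicate 2 it had 0 counts left in mock and was at least 19.7-fold higher.

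Genes of cell division were lower in the libraries labelled TubB. All 29 measured mitosis genes fell (adjusted p = 5.26e-10, and adjusted p = 0.317 with an estimated correlation), with a median of -0.91 on the log2 scale and the kinetochore kinase Bub1b (-1.71 ± 0.13), Plk1 (-1.44 ± 0.13), Cdc20 (-1.43 ± 0.12) and Ccnb2 (-1.40 ± 0.15) lowest. Of 32 DNA replication genes, 26 were lower and 1 higher (adjusted p = 4.09e-07, and adjusted p = 0.317 with an estimated correlation), with thymidine kinase Tk1 at -1.68 ± 0.20. Ribosome biogenesis genes were lower in 21 of 25 (adjusted p = 1.04e-06, and adjusted p = 0.308 with an estimated correlation), among them Dkc1 (-1.80 ± 0.12) and Nolc1 (-1.34 ± 0.09), while Myc itself and Odc1 (1.81 ± 0.07) were higher. Ribosomal protein genes were lower in 20 and higher in 1 of 39, with Rpl3 at -0.63 ± 0.07 (adjusted p = 0.00318, and adjusted p = 0.518 with an estimated correlation), and the list call was lost without TubB replicate 2 (adjusted p = 0.0909). Of 19 p53 targets, 11 were higher and 1 lower (adjusted p = 0.00289, and adjusted p = 0.373 with an estimated correlation), led by the death receptor Fas (3.70 ± 0.28), Btg2 (2.37 ± 0.18) and Mdm2 (2.21 ± 0.20). Unfolded protein response genes were lower in 15 and higher in 3 of 21 (adjusted p = 0.00109, and adjusted p = 0.373 with an estimated correlation), with Herpud1, which acts in the removal of misfolded proteins, at -1.29 ± 0.13. Without TubB replicate 2, Tk1 stood at -2.29.

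Among stress and housekeeping groups, Nrf2 targets were not called as a list by camera (adjusted p = 0.0944), with 12 of 26 higher and 4 lower, except without mock replicate 2 (adjusted p = 0.00751). Hmox1, heme oxygenase 1, rose from 335 ± 148 to 1591 ± 49.2 CPM (2.25 ± 0.41, adjusted p = 0.0105) and the peroxiredoxin Prdx1 by 2.17 ± 0.16. Lysosome genes were higher in 22 and lower in 1 of 32 (adjusted p = 5.19e-05, and adjusted p = 0.373 with an estimated correlation), with Ctsh at 2.44 ± 0.50 (3.34 without mock replicate 2) and Psap at 1.67 ± 0.07. Autophagy genes were higher in 12 of 22 (adjusted p = 0.000552, and adjusted p = 0.317 with an estimated correlation), with Atg13 at 1.49 ± 0.12 and Sqstm1 at 1.43 ± 0.12. Pattern receptor and Toll-like receptor signalling genes were higher in 20 and lower in 3 of 27 (adjusted p = 9.19e-06, and adjusted p = 0.186 with an estimated correlation), led by Nod1 (5.49 ± 0.36). Nod1 stood at 4.89 without mock replicate 1 and was 93.3-fold higher (95% interval 25.6 to 774) without mock replicate 2. Macrophage identity genes went both ways, 9 of 18 higher and 4 lower (adjusted p = 0.116 with camera and 0.000443 with fry), with Adgre1, which encodes F4/80, at 2.71 ± 0.15 and the Fc receptor Fcgr3 at 2.64 ± 0.13. Of the markers of other cell types, 4 were measured. S100a8 (2.91 ± 0.23) and Csf3r (1.56 ± 0.42), listed for neutrophils, and Xcr1 (5.03 ± 0.61), listed for dendritic cells, were higher in the same libraries. Xcr1 stood at 4.29 without mock replicate 1 and 4.31 without TubB replicate 1, and was 96.2-fold higher (95% interval 17.04 to 3823) without mock replicate 2. Itgax, listed for dendritic cells, was lower (-0.39 ± 0.13), a call lost with DESeq2 (adjusted p = 0.104), without mock replicate 1 (0.144) and without TubB replicate 2 (0.103).

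Other lists followed the same libraries. Immediate early and mitogen-activated kinase feedback genes were higher in 14 and lower in 3 of 22 (adjusted p = 0.00141, and adjusted p = 0.373 with an estimated correlation). Genes of JAK-STAT signalling, which carries interferon signals, were higher in 12 of 22 (adjusted p = 9.52e-05, and adjusted p = 0.186 with an estimated correlation). Complement and coagulation genes were higher in 8 and lower in 2 of 11 (adjusted p = 0.00157, and adjusted p = 0.186 with an estimated correlation). Matrix protease and adhesion genes were higher in 10 and lower in 2 of 14 (adjusted p = 0.00284, and adjusted p = 0.317 with an estimated correlation). Camera did not call amino acid response genes (adjusted p = 0.744), fatty acid oxidation (0.685), nuclear-retained RNA (0.651), osteoclast genes (0.482), metallothioneins (0.382), heat shock genes (0.172) or PI3K, AKT and mTOR components (0.0817). Fry, which asks whether a list's genes move one way without comparing them with other genes, called fatty acid oxidation (adjusted p = 0.0327, with 7 of 15 higher and 6 lower), metallothioneins (0.0408) and PI3K, AKT and mTOR components (0.00153) higher and heat shock genes (0.00522) lower. Adjusted over the list alone, Nrf2 targets had 12 higher and 5 lower, cholesterol synthesis 1 and 13, p53 targets 12 and 1, ribosomal proteins 1 and 21 and nuclear-retained RNA 1 and 1, and the other lists had the counts given over all genes. In all, camera called 20 lists higher and 8 lower, and 0 with an estimated correlation, and fry called 25 higher and 10 lower, all of camera's among them.

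The contrast of LPS_IFNg_TubB with LPS_IFNg, which shares no library with the last, asks what Tubuloside B does under the stimulus. As labelled, the same inflammatory genes were higher with the compound. Iigp1 and Serpina3g had 0 counts in the libraries labelled LPS_IFNg and were at least 2923-fold and 1819-fold higher in those labelled LPS_IFNg_TubB. Nos2 was higher by 5.22 ± 0.16, Ptgs2 by 5.32 ± 0.37, Ccl2 by 2.39 ± 0.08, Cxcl10 by 3.63 ± 0.37 (4.27 without LPS_IFNg replicate 1) and Hmox1 by 2.26 ± 0.41. Without LPS_IFNg replicate 1, Hmox1 was not called (1.94, adjusted p = 0.0557). Il6 was at least 218-fold higher. Without LPS_IFNg replicate 1 or 2, the bounds were 1438-fold or 1485-fold for Iigp1, 895-fold or 924-fold for Serpina3g and 107-fold or 110-fold for Il6. Igfbp4 (-3.85 ± 0.17), Cx3cr1 (-3.41 ± 0.22), Tfap4 (-2.97 ± 0.26), Ankle1 (-2.97 ± 0.28, and -3.88 without LPS_IFNg_TubB replicate 2) and Sapcd2 (-2.76 ± 0.26) fell most. EdgeR called 2903 genes higher and 2768 lower, or 1105 and 691 with a 2-fold minimum. Of the genes called in the contrast of TubB with mock, 2528 were higher in both contrasts and 2291 lower in both, against 764 and 688 for independent lists, and 0 were called in opposite directions. Across genes, which are not independent replicates, the fold changes of the contrasts had a Pearson correlation of 0.923 and a Spearman correlation of 0.891.

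In this contrast camera called 20 lists higher and 7 lower, and 0 with an estimated correlation, and fry called 24 higher and 10 lower, all of camera's among them. All 37 type I interferon genes and all 18 IFN-γ-inducible genes were higher (adjusted p = 2.35e-16 and 5.90e-16, against adjusted p = 0.314 and 0.210 with an estimated correlation), and all 22 NF-κB genes (adjusted p = 6.51e-12, against adjusted p = 0.215 with an estimated correlation). All 29 mitosis genes were lower, with Bub1b at -1.81 ± 0.14 and Plk1 at -1.68 ± 0.14 (adjusted p = 1.04e-10, against adjusted p = 0.314 with an estimated correlation). Tricarboxylic acid cycle genes were lower in 14 of 21 and higher in 0 (adjusted p = 9.20e-05, against adjusted p = 0.294 with an estimated correlation), with Idh2 at -1.40 ± 0.11 and Idh1 at -0.95 ± 0.10. Unfolded protein response genes were lower in 17 and higher in 3 of 21 (adjusted p = 0.000371, against adjusted p = 0.351 with an estimated correlation). Cytokines were higher in 9 of 11 (adjusted p = 1.03e-05, against adjusted p = 0.294 with an estimated correlation) and glycolysis genes higher in 19 and lower in 3 of 23 (adjusted p = 1.61e-05, against adjusted p = 0.314 with an estimated correlation). Counts adjusted over the list alone were the same for these lists. Ribosomal protein genes were lower in 18 and higher in 3 of 39 (adjusted p = 0.0283, against adjusted p = 0.635 with an estimated correlation), and that call was lost without LPS_IFNg replicate 2 (adjusted p = 0.0784) or LPS_IFNg_TubB replicate 2 (0.0561). Oxidative phosphorylation was called lower by fry (adjusted p = 0.0365) but not by camera (adjusted p = 0.0810), except without LPS_IFNg replicate 1 (0.0122). Liver X receptor targets (adjusted p = 0.0192 with fry and 0.0558 with camera) were called lower by camera without TubB replicate 2, LPS_IFNg replicate 2 or LPS_IFNg_TubB replicate 1. Nrf2 targets and macrophage identity genes were called higher by camera without LPS_IFNg replicate 2. Fry also called heat shock genes lower (adjusted p = 0.00220), and class II presentation (0.000284), macrophage identity (0.000298), PI3K, AKT and mTOR components (0.00160) and fatty acid oxidation (0.0285, with 5 of 15 higher and 5 lower) higher. Markers of other cell types moved here too. S100a8 (3.07 ± 0.25) and Csf3r (1.43 ± 0.43) were higher, and Xcr1, with 2 counts over LPS_IFNg and 121 over LPS_IFNg_TubB, was 69.5-fold higher (95% interval 18.8 to 581). Xcr1 was 34.2-fold higher (9.27 to 286) without LPS_IFNg replicate 1 and at least 23.5-fold without LPS_IFNg replicate 2. Csf3r was not called without LPS_IFNg replicate 2 (adjusted p = 0.0679) or LPS_IFNg_TubB replicate 2 (0.101). Itgax was lower (-0.34 ± 0.14, adjusted p = 0.0420), a call lost with DESeq2 (0.171), with no count filter (0.0773) and without any 1 library of mock, LPS_IFNg or LPS_IFNg_TubB (0.0520 to 0.163). Whether lists differ between the 2 contrasts is tested by the interaction.

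**Figure D2:**
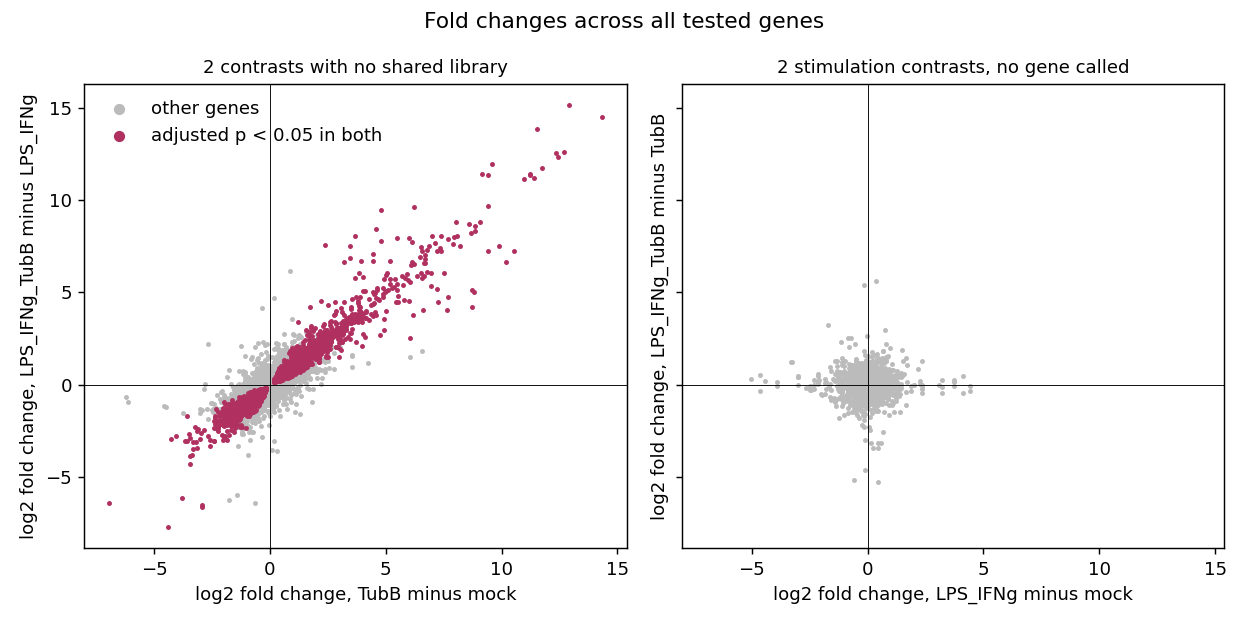
Log2 fold changes of 11081 genes, 1 point per gene. On the left, TubB minus mock (x) against LPS_IFNg_TubB minus LPS_IFNg (y), with genes called in both in red, follow the diagonal (Pearson 0.923), and on the right, LPS_IFNg minus mock (x) against LPS_IFNg_TubB minus TubB (y), where 0 genes were called, gather around 0.

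The interaction asks whether the effect of Tubuloside B differed with and without the stimulus. Nos2 differed by -0.05 ± 0.19 between the 2 effects (95% interval -0.49 to 0.40), Ccl2 by 0.04 ± 0.11 (-0.19 to 0.27), Ptgs2 by -0.03 ± 0.50 (-1.37 to 1.31), Cxcl10 by 0.31 ± 0.61 (-0.94 to 1.56) and Hmox1 by 0.01 ± 0.55 (-1.49 to 1.51). EdgeR called 0 of 11081 genes, with 277 (2.5%) at an unadjusted p under 0.05, fewer than chance alone would give. DESeq2 and limma-voom also called 0. The interval excluded a 2-fold difference for 8195 genes. Mitosis genes had a median of -0.12 (adjusted p = 0.328) and complement and coagulation genes one of 0.08 (adjusted p = 0.328), and 0 of 39 lists were called. Single libraries changed this, but leaving 1 out also unbalances the replicate numbers, so these list calls cannot be told apart from a difference between replicates. Without TubB replicate 1, 4 lists were called higher and 2 lower, with type I interferon (adjusted p = 7.31e-06) the first of those higher and mitosis (2.10e-05) the first of those lower. Without TubB replicate 2, type I interferon was called lower instead (adjusted p = 0.0187). Without LPS_IFNg_TubB replicate 2, 2 lists were higher (type I interferon and immediate early genes, adjusted p = 0.0168 each) and mitosis lower (0.00266), and without mock replicate 2, Nrf2 targets were lower (0.00877).

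The contrast of LPS_IFNg with mock asks what the stimulus does alone. No marker of the stimulus was called between the libraries so labelled. Nos2 differed by 0.14 ± 0.14 on the log2 scale (95% interval -0.19 to 0.47), Ccl2 by -0.02 ± 0.08 (-0.18 to 0.14), Ptgs2 by 0.01 ± 0.40 (-1.08 to 1.10), Cxcl10 by -0.01 ± 0.54 (-1.12 to 1.10) and Hmox1 by -0.10 ± 0.40 (-1.19 to 0.98). Il1b had 5 counts over the libraries labelled LPS_IFNg and 1 over those labelled mock, a ratio of 5.89 with a 95% interval of 0.660 to 279. Without mock replicate 1 this ratio was 2.90 (0.324 to 137) and without LPS_IFNg replicate 2 it was 9.28 (0.919 to 457). Il1a had 11 counts over LPS_IFNg and 3 over mock, a ratio of 4.32 whose counting interval of 1.14 to 24.1 excluded 1, while edgeR, which adds the variation between replicates, did not call it (2.01 ± 1.04, adjusted p = 1). The Il1a ratio was 2.20 (0.580 to 12.3) without mock replicate 2, 7.74 (1.99 to 43.7) without LPS_IFNg replicate 2 and at least 2.13 without mock replicate 1. Of the type I interferon genes, Herc6 (-0.49 ± 0.28) and Isg20 (0.95 ± 0.77) had the smallest p, and of the IFN-γ list Irf8 (0.24 ± 0.12) and Batf2, with 1 count over LPS_IFNg and 5 over mock. EdgeR called 0 of 11081 genes, with 247 (2.2%) at an unadjusted p under 0.05, fewer than chance alone would give. DESeq2, limma-voom and limma on the rlog values also called 0. The interval excluded a 2-fold change for 9269 genes. Camera called 0 of 39 lists, with ribosomal proteins lowest in p (median -0.05, adjusted p = 0.0882). Without mock replicate 1, JAK-STAT genes were called higher and immediate early genes and Nrf2 targets lower (adjusted p = 0.0214 each). Without mock replicate 2, Nrf2 targets (0.00266) and p53 targets (0.0381) were called higher, and without LPS_IFNg replicate 2 ribosomal proteins lower (0.0286).

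Because 0 genes were called for the stimulus, the share of stimulus-responsive genes that Tubuloside B moved back had no genes to be taken over. Across genes, the fold changes of LPS_IFNg minus mock and LPS_IFNg_TubB minus LPS_IFNg had a Spearman correlation of -0.11. The shared LPS_IFNg libraries alone gave -0.46 in 100 simulations without effects (range -0.49 to -0.44). In these simulations no group differed, whereas 51.2% of genes were called between LPS_IFNg_TubB and LPS_IFNg in the data. Such differences weaken the correlation, so -0.11 and -0.46 are not comparable. The covariance of the fold changes, which is not scaled by their spread, was -0.0278, against -0.0284 simulated.

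The contrast of LPS_IFNg_TubB with TubB asks what the stimulus does in the presence of the compound, and again no marker was called between the libraries so labelled. Nos2 differed by 0.09 ± 0.13 (95% interval -0.20 to 0.39), Il6 by 0.11 ± 0.34 (-0.73 to 0.96), Il1b by 0.20 ± 0.28 (-0.38 to 0.78), Ptgs2 by -0.02 ± 0.29 (-0.80 to 0.77), Ccl2 by 0.02 ± 0.08 (-0.14 to 0.18), Cxcl10 by 0.30 ± 0.26 (-0.23 to 0.83) and Hmox1 by -0.09 ± 0.38 (-1.13 to 0.94). Cenpa, a centromere histone, differed by -0.57 ± 0.15 and the glutathione transferase Gstm1 by -0.59 ± 0.23, both with an adjusted p = 0.999. EdgeR called 0 of 11081 genes, with 269 (2.4%) at an unadjusted p under 0.05, fewer than chance alone would give. DESeq2, limma-voom and limma on the rlog values also called 0. With the replicate number as a block within these groups alone, chosen after the data were seen, edgeR called 5 genes: Sap30 (0.48 ± 0.10), Bc1 (0.40 ± 0.08), Cebpb (0.32 ± 0.07) and Malat1 (0.25 ± 0.06) higher, and AY036118 (-0.39 ± 0.07) lower. That fit leaves fewer residual degrees of freedom than the 4 of the main fit. With the block over all 8 libraries edgeR called 0. The interval excluded a 2-fold change for 9273 genes. Camera called 0 of 39 lists, with DNA replication lowest in p (adjusted p = 0.467). Leaving out a library of these groups unbalances the replicate numbers, so the list calls that follow cannot be told apart from a difference between replicates. Without TubB replicate 1, 11 lists were called higher and 5 lower, with type I interferon (adjusted p = 8.05e-09) and mitosis (7.49e-07) lowest in p. Without TubB replicate 2, type I interferon was called lower instead (0.000217). Without LPS_IFNg_TubB replicate 2, type I interferon was higher (0.00434), and mitosis (0.000612), cholesterol synthesis (0.0129) and DNA replication (0.0237) were lower.

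**Figure D3:**
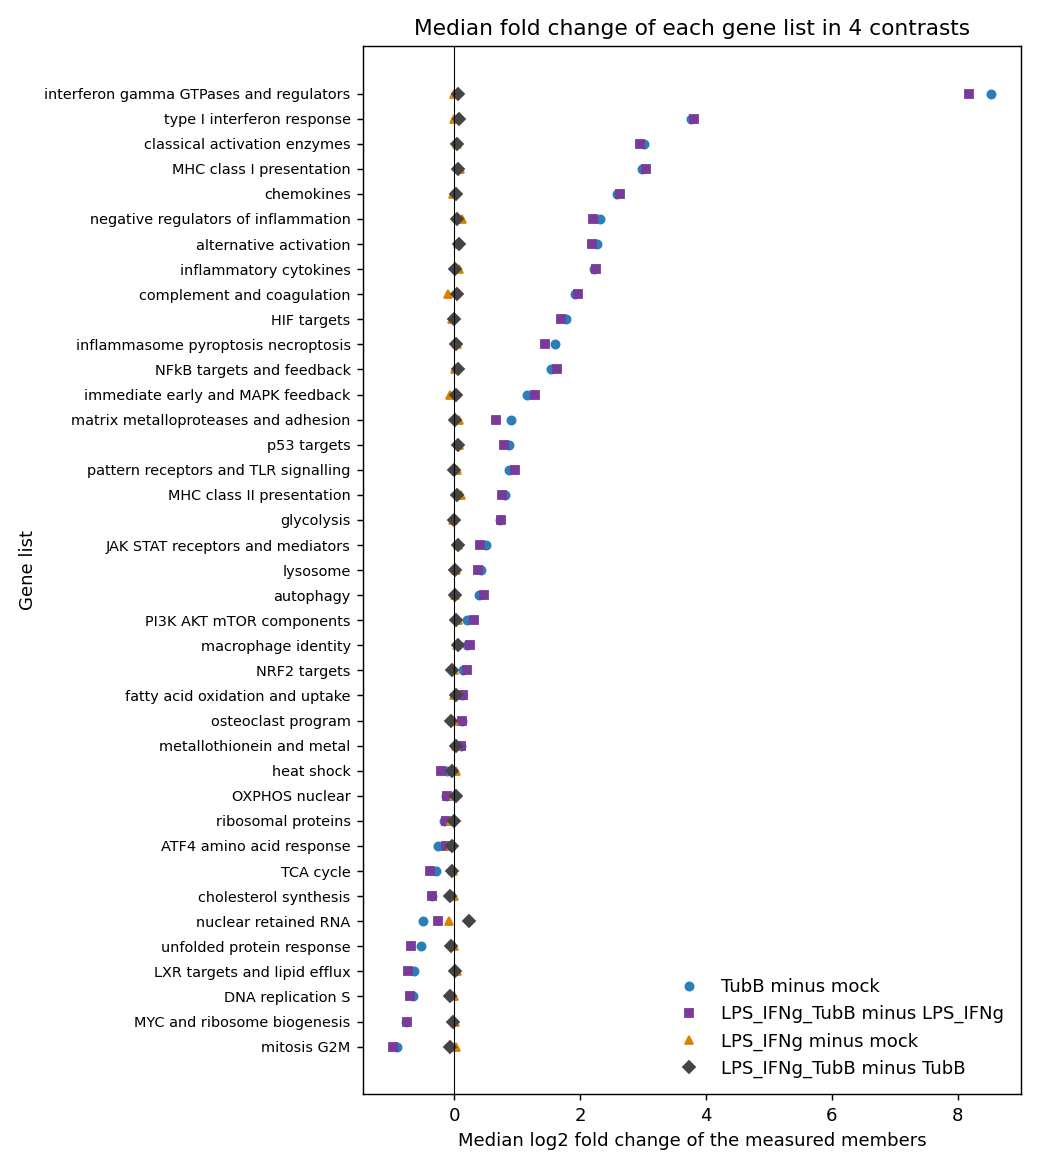
Median log2 fold change of the measured members (x) of each of 39 gene lists (y) in 4 contrasts, 1 symbol per contrast. As labelled, the 2 contrasts of compound with no compound lie together, from the IFN-γ list at 8.52 and 8.18 to the mitosis list at -0.91 and -0.97, and the 2 contrasts of stimulus with no stimulus lie near 0. With the 8 members of few counts at their bound or count ratio, the IFN-γ medians were 8.01 and 7.95.

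The libraries labelled LPS_IFNg_TubB and mock carry neither of the labels that the marker genes go against. Exchanges that involve these labels were not tested. The contrast of LPS_IFNg_TubB with mock was added after the data were seen, and gives, as labelled, the stimulus and the compound together. Serpina3g was at least 2144-fold higher in the libraries labelled LPS_IFNg_TubB, Nos2 was higher by 5.36 ± 0.16, Ptgs2 by 5.33 ± 0.37, Ccl2 by 2.37 ± 0.08, Cxcl10 by 3.62 ± 0.36 and Hmox1 by 2.15 ± 0.40. Igfbp4 (-3.79 ± 0.17), Cx3cr1 (-3.25 ± 0.22), Tfap4 (-2.76 ± 0.26), Ankle1 (-2.73 ± 0.28) and Ptgs1 (-2.60 ± 0.17) fell most. EdgeR called 2946 genes higher and 2801 lower. Without LPS_IFNg_TubB replicate 1, Hmox1 was not called (2.17, adjusted p = 0.0504), and without LPS_IFNg_TubB replicate 2, Ankle1 stood at -3.64. Serpina3g was at least 1054-fold or 1090-fold higher without mock replicate 1 or 2. Camera called 20 lists higher and 8 lower, and 0 with an estimated correlation, and fry called 25 higher and 10 lower. S100a8 (2.84 ± 0.23), Csf3r (1.61 ± 0.42) and Xcr1 (4.72 ± 0.63), listed for other cell types, were higher. Itgax, listed for dendritic cells, went the other way. Before TMM scaling it had 46.8 and 42.3 CPM in mock and 30.6 and 30.3 in LPS_IFNg_TubB. Xcr1 stood at 3.98 without mock replicate 1 and was 83.3-fold higher (95% interval 14.7 to 3317) without mock replicate 2, and Csf3r was not called without LPS_IFNg_TubB replicate 2 (adjusted p = 0.0547). Oxidative phosphorylation was lost from camera's calls (adjusted p = 0.0431) without mock replicate 2 (0.0928), either TubB library (0.0615 and 0.0621) or either LPS_IFNg_TubB library (0.0554 and 0.0505). Liver X receptor targets (adjusted p = 0.0670) were called lower by camera without mock replicate 2 or LPS_IFNg_TubB replicate 1. Nrf2 targets (adjusted p = 0.150) were called higher by camera without mock replicate 2. The part of each treatment in this contrast cannot be separated by it.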

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

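The block within the compared groups and every setting of LPS_IFNg_TubB minus mock were chosen after the data were seen. Counts of called genes stayed within 1.5 times under RLE factors, both other count filters, DESeq2, limma-voom, limma on rlog values and each left-out library, in every contrast of 2 groups and the interaction, and with the compared groups alone in every contrast of 2 groups (the interaction uses all 4 groups and has no such value). A 2-fold minimum lowered them, by its construction, to 1105 higher and 691 lower for LPS_IFNg_TubB minus LPS_IFNg, 1103 and 626 for TubB minus mock, and 1133 and 686 for LPS_IFNg_TubB minus mock. Without 1 library, genes called higher and lower ranged from 2367 to 3035 and 2121 to 2822, from 2408 to 2987 and 2127 to 2810, and from 2469 to 3066 and 2162 to 2898 in these contrasts. The lone library left in a group is then assumed to vary like the other groups. Leaving out a library of a compared group also unbalances the replicate numbers, and 15 type I interferon genes differed between replicates 1 and 2. List calls that change in this way cannot be told apart from a difference between replicates. Same-numbered libraries deviated together for mock with LPS_IFNg (correlation 0.145) and TubB with LPS_IFNg_TubB (0.263) but not for the 4 other pairs of groups (-0.0927 to 0.00183). The numbers were therefore not taken as pairing the samples over all groups, but may pair the libraries within those 2 pairs. Their contrasts, fitted without a block, keep such shared variation in the error. In the compared groups only, the block raised genes at an unadjusted p under 0.05 from 343 to 623 for LPS_IFNg minus mock. For LPS_IFNg_TubB minus TubB they rose from 164 to 427. With the replicate block, TubB minus mock had 2941 genes higher and 2788 lower, LPS_IFNg_TubB minus LPS_IFNg 2940 and 2813, and the stimulation contrasts and the interaction 0. With the replicate block in the compared groups only, LPS_IFNg_TubB minus TubB had 4 genes higher (Bc1, Sap30, Malat1 and Cebpb) and 1 lower (AY036118). These genes were named after their values were seen, and the cause was not tested. The other contrasts moved by less than 1.5 times. Such fits within the compared groups leave fewer residual degrees of freedom than the main fit. List calls depended on the correlation: with an estimated one, 0 were called higher and 0 lower in TubB minus mock, LPS_IFNg_TubB minus LPS_IFNg and LPS_IFNg_TubB minus mock. That test has only the 4 residual degrees of freedom of the design, so its 0 calls cannot tell weak lists from low power. Fry, which does not compare a list with other genes, called 25 higher and 10 lower, 24 and 10, and 25 and 10 in these contrasts, against 20 and 8, 20 and 7, and 20 and 8 with camera. Without 1 library, lists called higher and lower ranged from 0 to 2 and 0 to 2 for LPS_IFNg minus mock, 0 to 4 and 0 to 2 for the interaction, and 0 to 11 and 0 to 5 for LPS_IFNg_TubB minus TubB, the most without TubB replicate 1, and the cause was not tested. They ranged from 20 to 22 and 7 to 9 for TubB minus mock, 20 to 22 and 6 to 8 for LPS_IFNg_TubB minus LPS_IFNg, and 20 to 21 and 7 to 8 for LPS_IFNg_TubB minus mock. The Spearman correlation of the compound's 2 effects ranged from 0.834 to 0.853 without 1 library, against 0.891, and was 0.848 with the filter of 1 CPM. Leaving out a library also let more genes past the filter (11390 to 11566, against 11081), and the filter of 1 CPM kept 11852. The lower correlation therefore cannot be told apart from a change in the genes tested. Of 12427 values of single named genes under alternatives, 12332 stayed on the same side of the threshold, 93 lost the call and 2 gained one. Among genes called in the main fit or the alternative, 0 reversed direction. Changes of direction in genes called in neither were not counted. Depth limited genes with under about 10 counts per group, such as Il6 and Il1b in the libraries labelled mock and LPS_IFNg.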

Other observations

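The tests of the label conflict, of the alternate copies and of library depth were chosen after their results were seen, the splits were sorted by structure after their counts were seen, and the reading of the selenium test was narrowed after its value was seen. With the group as a term, 39 of 11081 genes differed between replicates 1 and 2 (edgeR, adjusted p under 0.05), 34 lower and 5 higher in replicate 2, with 691 genes at an unadjusted p under 0.05. These genes were named after their values were seen. Of the 39, 15 belonged to the type I interferon list, among them Isg15 (-1.05 ± 0.14 on the log2 scale, lower in 4 of 4 groups), Ifit2 (-0.74 ± 0.09, 4 of 4), Rsad2 (-1.01 ± 0.10, 3 of 4) and Usp18 (-0.67 ± 0.10, 4 of 4), genes that respond to interferon. The selenoprotein genes Gpx1 (-0.63 ± 0.05, adjusted p = 3.36e-09), Selenow (-1.07 ± 0.09) and Selenoh (-0.65 ± 0.09) were lower in replicate 2 of every group, and Sephs2, which makes the selenium donor for selenoprotein synthesis, was higher (0.38 ± 0.06, 4 of 4). Of 32 splits of the 8 libraries into 4 and 4, 4 gave as many genes, the real one with 39 included, and the highest other gave 299. Splits that keep some groups whole came in mirrored pairs, each the same test with its sign reversed. The 32 splits are therefore not all distinct, and the splits with 299 genes are such a pair. The 6 splits that part TubB and LPS_IFNg_TubB by replicate number gave 22 to 299 genes and the 26 others 0 to 4, with mirrored pairs in both sets. The splits that gave as many genes therefore share this structure with the real one, and their number does not decide whether the count arose by chance.

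The first pattern is the conflict of the labels with the marker genes. A numbering of the count table that differs from the authors' rlog table is argued against, because 8 of 8 libraries correlated best with the rlog column of their own number, although an error made before both tables would not show. An exchange of the labels of the LPS_IFNg and TubB groups may account for the pattern: over 70 members of the 3 activation lists, the larger of the median differences of LPS_IFNg minus mock and LPS_IFNg_TubB minus TubB was 0.061 on the log2 scale, so each group has a partner out of place. It cannot be told apart from Tubuloside B inducing these genes by itself with an inactive stimulus, since 0 of the 70 members were called between LPS_IFNg and mock and both need this, so the design confounds them. Under an exchange of LPS_IFNg and TubB, the contrasts with 0 calls would be those of the compound. The interaction, unchanged by that exchange, would still have 0. Exchanges that involve the labels mock or LPS_IFNg_TubB were not tested.

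The second pattern is that Tnf, Psmb8, Tap1 and H2-Aa, in the major histocompatibility region of chromosome 17, held 0 counts in the 8 libraries. Loss of reads shared with alternate-locus copies may account for this. Of ribosomal protein genes, which every cell uses, 3 of 4 with a numbered copy (75%; Rps10, Rps18 and Rps28) held 0 counts, against 0 of 75 without one. Of all 1740 symbols with a copy, 71.2% held 0 counts. Because only 18955 of all 42454 rows held any count, this share alone is weak evidence. No biological explanation was tested, and whether Tnf changed stays open.

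The third pattern is the lower Gpx1, Selenow and Selenoh in replicate 2. Loss of short transcripts is argued against, since 631 genes no longer than the longest of the 3 had a median difference of 0.000876, and so is library depth, since the larger library had the lower Gpx1 in only 2 of 4 groups. A lower selenium supply in replicate 2 might lower the messages of this sensitive class, but a further member, Msrb1, differed by -0.15 ± 0.08 (adjusted p = 0.814). The bound set beforehand to argue against it, a difference under 0.2, was met by less than this SE, so selenium stays open, as does any culture difference, which was not tested. The median of 9 insensitive selenoprotein genes was -0.03.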
